A study of Mus musculus with 12 samples.

How the data were processed

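Chromatin from pro-B cells of Rag1-deficient C57BL/6 mice was crosslinked with formaldehyde, sonicated and immunoprecipitated, and the libraries were sequenced on an Illumina instrument, per the labels' protocols. The 12 samples are 7 antibody libraries and 5 inputs, each a group of 1. Peak lists were used for the CTCF and Rad21 libraries, and the other 10 samples were not analysed here.

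The submitters' processing notes name Bowtie 0.12.9, MACS2 2.0.10 and the mm9 build, without saying what each was used for. Per the file headers, each list was called for an antibody library against an input library, so peaks were called per sample and not on pooled samples. The header of the Rad21 list names its input without an antibody, while the CTCF header names a CTCF input. Caller settings, thresholds and read filters are not given in the sources used here. The fifth column of each list holds the score of a peak as the authors deposited it. Its scale is not given in the sources used here. Every score is at least 50.0, and the peaks are numbered in order of falling score. The value of 3100 is repeated at the top of both lists, so peaks with it are tied. Scores were compared only within a list, to rank, filter, match or summarise peaks. For the check of reads that map to several V segments, CTCF scores were also multiplied by a factor, although their scale is not given. Since the lists contain peaks past a threshold and no read counts, the depth is unknown. The number of peaks that pass a threshold generally depends on depth, so the lengths of the lists and the shares computed from them can move with depth in a way that these files do not show.

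Starts in the lists count from 0 and were converted to count from 1. Peaks were called shared when they overlapped by at least 1 bp. Shares carry Wilson 95% intervals over the genome and exact binomial intervals in regions, and counts carry exact Poisson intervals. The interval for Rad21 peaks per 100 CTCF peaks came from an exact binomial on the share of Rad21 among both counts. It treats the counts as independent, although most Rad21 peaks lay on CTCF peaks, so it may be too wide. Random overlap was the mean of 100 placements of the peaks on their own chromosomes with a fixed seed, either anywhere or within 100 kb bins holding a peak of either list. With 1 library per antibody no test across libraries is possible. Percentiles among windows or runs and matched draws describe these libraries.

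The antigen receptor regions are whole 1 Mb windows set from general knowledge of mm9, and a peak belongs to a region by its centre. Density in a region was compared with all windows of the same length that start on a 1 Mb grid and hold a peak of either list. Spacing was compared with runs of as many neighbouring peaks elsewhere, each run starting 10 peaks after the last, and with stretches of at least 50 peaks between the 2 widest gaps of other 4 Mb windows. Score-matched draws took, for each peak, a peak elsewhere from the same of 50 score classes, 10000 times (2000 times for medians of Rad21 scores). The gene table used for names belongs to another build, GRCm38.p6, and served only for the names and order of genes in the receptor loci. None of its coordinates were used.

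Peaks and regions were named by a rule set before the data were examined, except where the text says that they were chosen after. The receptor regions, the definition of a shared peak and most of the alternatives were also set before. The rule named the 5 peaks of highest score in each list and in the Igh region of each list, and the first and last peak and the 3 widest gaps of the Igh region. It also named the 5 densest 1 Mb windows of each list and the chromosomes of highest and lowest density, which for Y was not computed. Peaks tied at 3100 were taken in the order of the list. Planned results that need gene positions or sequence of mm9, namely promoter shares, gene lists with promoter peaks, distances from V genes and CTCF motifs, were not run. The V-side block of Igh was bounded after the data were seen.

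Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. The functions were tested on simulated lists of 41820 and 31070 peaks. There a planted overlap of 80.0% was recovered as 80.3% (80.3% is expected with random extra overlaps). A direct count was made for chromosome 19 only, and no peak there was classed differently from it. A planted offset of -60 bp over 197 pairs was recovered as -63.5 bp, and a planted coefficient of variation of 0.5 as 0.498. Alternatives covered the overlap definition, score threshold, peak merging, window size and region boundaries.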

Results

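The study examined how V genes of the mouse immunoglobulin heavy chain locus, Igh, are used in rearrangement, and its chromatin immunoprecipitation sequencing (ChIP-seq) profiled pro-B cells. These cells are the B cell precursors in which Igh recombines. They were taken from the bone marrow of C57BL/6 mice lacking Rag1, whose product is part of the recombinase, so that the locus stays in its unrearranged form. CD19-positive cells were enriched on magnetic beads. The 12 libraries comprised 7 antibody libraries and 5 input controls, with 1 library per antibody. Peak lists for CTCF and Rad21 are described here. CTCF is a zinc finger protein that binds insulator sites, and Rad21 is a subunit of cohesin, the ring complex that holds chromatin loops. The other 10 libraries, among them those for H3ac, H3K27me3, H3K4me2, H3K4me3 and RNA polymerase II, were not analysed here. No list has a replicate, so no comparison has a replicate check and no p-value is given. Intervals cover counting error only. The lists hold no read counts, so the depth of the libraries is unknown.

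The CTCF list held 41820 peaks and the Rad21 list 31071, or 74.3 Rad21 peaks per 100 CTCF peaks. CTCF peaks covered 20.9 Mb of the genome with a median width of 478 bp (quartiles 357 and 616 bp). Rad21 peaks covered 10.1 Mb with a median width of 308 bp (quartiles 244 and 384 bp). The authors' peak score, which has no stated scale and is used here only within a list, had a median of 217 for CTCF and 152 for Rad21. The highest CTCF score, 3188, was at chromosome 2, 11524665 to 11525373 (mm9, as for all positions), and this peak overlapped a Rad21 peak. The highest Rad21 score, 3137, was at chromosome 2, 166389339 to 166390328, and this peak overlapped a CTCF peak. The next 7 Rad21 peaks were tied at 3100. By the numbering of the list they were led by a peak in the Igh region, followed by chromosome 13, 111158804 to 111159255, chromosome 16, 30251902 to 30252650, and chromosome 17, 4626108 to 4626770, and each of these overlapped CTCF. The second CTCF peak, at chromosome 17, 48237626 to 48238485 (score 3147), had no Rad21 peak over it. Of 26 CTCF peaks tied at 3100, the first in the list was at chromosome 10, 127111666 to 127112471, and overlapped Rad21. The next, at chromosome 10, 79627541 to 79628439, and chromosome 11, 117963954 to 117965892, did not.

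The comparison of both lists asked where cohesin and CTCF occupied the same sites. Of the CTCF peaks, 27039 overlapped a Rad21 peak by at least 1 bp, which is 64.7% (Wilson 95% interval 64.2 to 65.1). Of the Rad21 peaks, 27309 overlapped a CTCF peak, which is 87.9% (87.5 to 88.3). Most Rad21 peaks in these cells lay on CTCF peaks, whereas 14781 CTCF peaks had no Rad21 peak over them and 3762 Rad21 peaks had no CTCF peak. Random placement of the peaks on their own chromosomes gave an overlap of 1.05% for CTCF (range of 100 placements 0.913 to 1.18) and 1.43% for Rad21 (1.19 to 1.57). Placement within 100 kb bins that held a peak gave 1.82% and 2.46%.

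CTCF peaks shared with Rad21 had a median score of 361 and a median width of 527 bp, against 94.8 and 393 bp for those without Rad21. Rad21 peaks shared with CTCF had a median score of 178, against 65.4 for those without CTCF. The share of CTCF peaks overlapping Rad21 was 93.7% in the highest-scoring 10% of the list, 96.4% in the next 10% and 18.9% in the lowest 10%. For Rad21 the share fell from 99.7% in the highest-scoring 10% to 54.4% in the lowest.

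**Figure D1:**
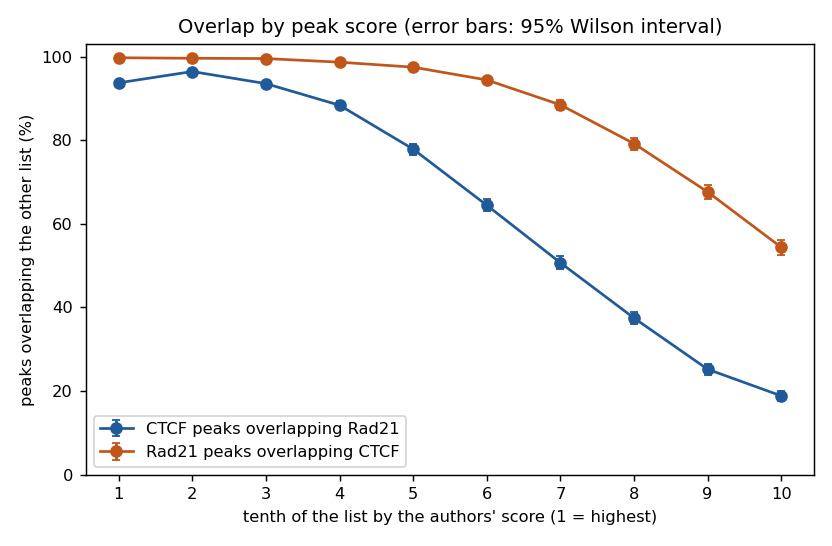
Share of peaks overlapping the other list (percent) in steps of 10% of the CTCF list (blue) and the Rad21 list (orange) by the authors' score, from the highest (1) to the lowest (10); error bars are Wilson 95% intervals. The CTCF share is 93.7% in the first group and 18.9% in the last, and the Rad21 share 99.7% and 54.4%.

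The Igh region was compared with the rest of the genome because the study concerned this locus. It was taken as chromosome 12, 114000001 to 118000000, which holds the locus and its flanks. By gene order, with rising coordinates, Tmem121 is followed by the constant region genes from Igha to Ighm. The J and D segments come next, then the V segments from Ighv5-1 to Ighv1-86, and then Zfp386. The region held 180 CTCF peaks (exact Poisson 95% interval 155 to 208), or 45.0 per Mb, against 16.3 per Mb in the genome. It held 173 Rad21 peaks (148 to 201), or 43.2 per Mb, against 12.1 per Mb. Of 2562 windows of 4 Mb with a peak in either list, 95.9% had fewer CTCF peaks and 99.6% had fewer Rad21 peaks than Igh. The window from 116000001 to 117000000 held 58 Rad21 peaks and was among the 5 densest 1 Mb windows for Rad21. The median window with peaks held 11.

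Of the CTCF peaks in the Igh region, 147 overlapped a Rad21 peak, which is 81.7% (exact 95% interval 75.2 to 87.0), against 64.6% (64.1 to 65.0) in the rest of the genome. The Rad21 peaks of the region overlapped CTCF in 86.7% (80.7 to 91.4), against 87.9% elsewhere, a difference within the interval. CTCF peaks of the region had a median score of 285, against 217 in the rest of the list. With the top 50% of the CTCF list by score, the share was 94.3% (88.1 to 97.9, 106 peaks) in Igh and 89.9% in the rest of the genome, a difference within the interval.

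The first CTCF and Rad21 peaks of the region were at 114038464 to 114039257 and 114038631 to 114039083, and the last at 117892212 to 117892511 and 117892296 to 117892449. A group of strong peaks lay on the low-coordinate side of the region, below a wide gap. Between 114454087 and 114462801, a stretch of 8.71 kb, lay 5 CTCF peaks and 8 Rad21 peaks. The CTCF peaks at 114455106 to 114456654, 114457853 to 114459971 and 114460124 to 114461499 had scores of 2207, 2745 and 3100, the 3 highest in the region. The next highest, at 114384076 to 114384799 (score 1622) and 114393672 to 114394683 (score 1522), lay nearer to the start of the region. The Rad21 peak at 114460156 to 114461587 had a score of 3100 and overlapped the CTCF peak at 114460124. The other Rad21 peaks with high scores here were at 114458661 to 114459275 (score 1212) and 114456054 to 114456489 (score 1105). A group of CTCF sites downstream of the constant region genes, near the 3′ enhancers, is known from the literature, but the peaks were not assigned to it here because no mm9 gene annotation was used. The group was singled out after its values were seen, as were the peaks that border the gap described next.

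At higher coordinates than this group followed 260 kb without a CTCF peak, from 114462802 to 114723235. Where the constant, J and D genes lie relative to the group and the gap was not examined, since no mm9 gene positions were used. The Rad21 list had a gap of 257 kb at the same place, from 114466796 to 114723362. The gap ended at a closely spaced pair of CTCF peaks, at 114723236 to 114723876 (score 96.3) and 114725651 to 114726347 (score 691), separated by 1.77 kb. Each overlapped a Rad21 peak, with scores of 94.9 and 741. A pair of CTCF sites between the V and D segments is known as an insulator of Igh recombination, and these peaks were likewise not assigned to it. The next CTCF peak that overlapped Rad21 was at 114816278 to 114817031 (score 312), and a gap of 74.8 kb lay before it. The largest gap of the region, 302 kb for CTCF (117520121 to 117822301) and 339 kb for Rad21 (117519876 to 117858450), lay at the far end. The third widest Rad21 gap, 99.1 kb from 117316427 to 117415552, lay at lower coordinates.

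Between both gaps, from 114723236 to 117520120, 132 CTCF peaks were spread over 2.80 Mb, or 47.2 per Mb (39.5 to 56.0). This stretch is called the V-side block below and was bounded by the gaps after the data were seen. Its name follows the gene order, and no V segment was placed in it by position. The part of the region below the block, 114000001 to 114723235, had 59.5 CTCF peaks per Mb (43.0 to 80.1). This length includes the 260 kb gap, whereas the block leaves out the gaps beside it, so both densities are not alike. All 43 CTCF peaks of that part lay between 114000001 and 114500000 (31.1 to 57.9). The fullest of the 500 kb windows from 114500001 to 117500000 held 30 (20.2 to 42.8). The block held 131 Rad21 peaks, and 111 of its CTCF peaks, 84.1% (76.7 to 89.9), overlapped one. Its strongest Rad21 peaks were at 117205793 to 117206121 (score 1251) and 117110684 to 117111041 (score 1090). In steps of 500 kb from 114500001 to 117500000, the median CTCF score was 367, 239, 170, 176, 312 and 303, lowest in the middle of the block. Median Rad21 scores in the same windows were 120, 119, 120, 139, 191 and 212.

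**Figure D2:**
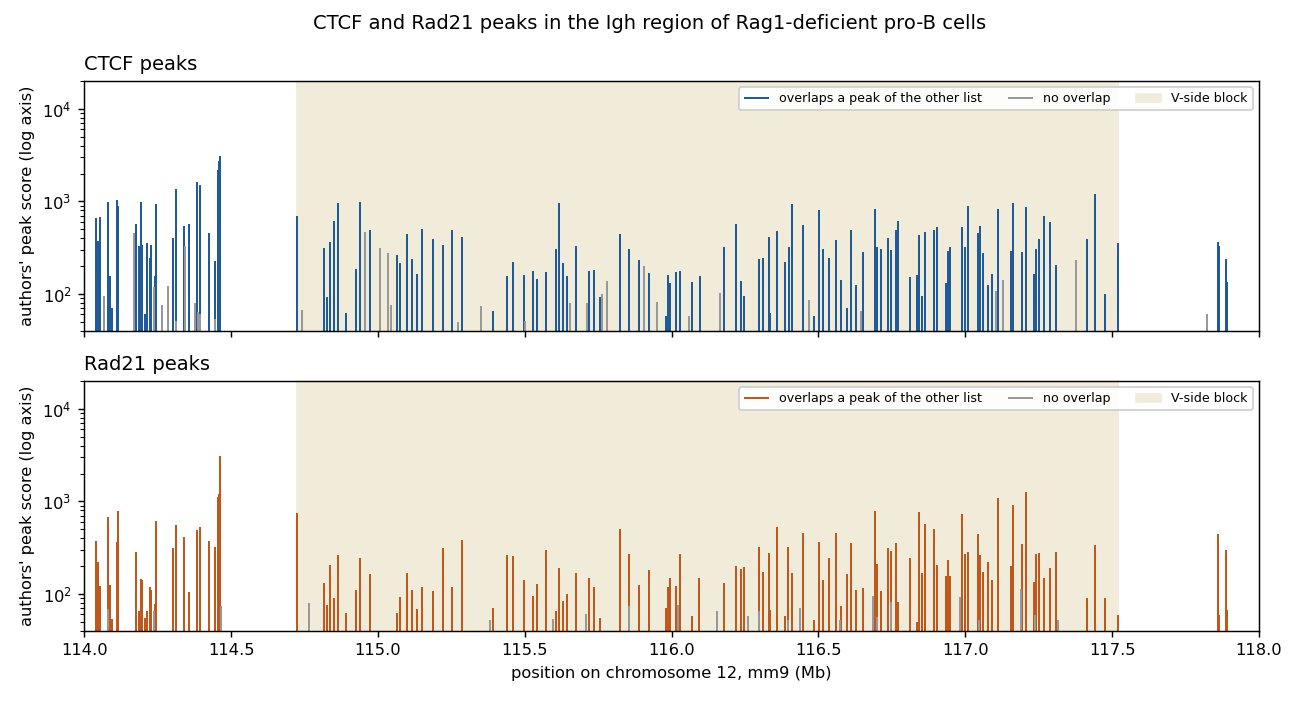
Map of CTCF (top) and Rad21 (bottom) peaks on chromosome 12, 114000001 to 118000000 in mm9 (axis in Mb); the height of a line is the authors' score on a log axis, coloured lines overlap a peak of the other list and grey lines do not. The shaded V-side block holds 132 CTCF and 131 Rad21 peaks, and the strongest group of peaks stands at the left edge of the 260 kb gap before it.

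CTCF peaks of the block were more evenly spaced than runs of CTCF peaks elsewhere. Their centres were a median of 17.3 kb apart (quartiles 11.9 and 28.7 kb), and 3 distances were under 5 kb. The coefficient of variation of these distances was 0.647, lower than in each of 3912 runs of 132 neighbouring CTCF peaks elsewhere, of which the lowest had 0.916. Rad21 peaks of the block had a coefficient of 0.822, below the lowest of 2839 runs (0.936), with 14 distances under 5 kb. The block was bounded by wide gaps, which takes the longest distances out of it. Among stretches of at least 50 peaks between the 2 widest gaps of other 4 Mb windows, 0 of 273 were as even for CTCF (lowest coefficient 0.840) and 3 of 152 for Rad21. With the top 50% of each list by score the block's coefficients were 1.14 for CTCF and 0.980 for Rad21, and 6.89% of 1945 CTCF runs and 2.03% of 1428 Rad21 runs were as even as the block.

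**Figure D3:**
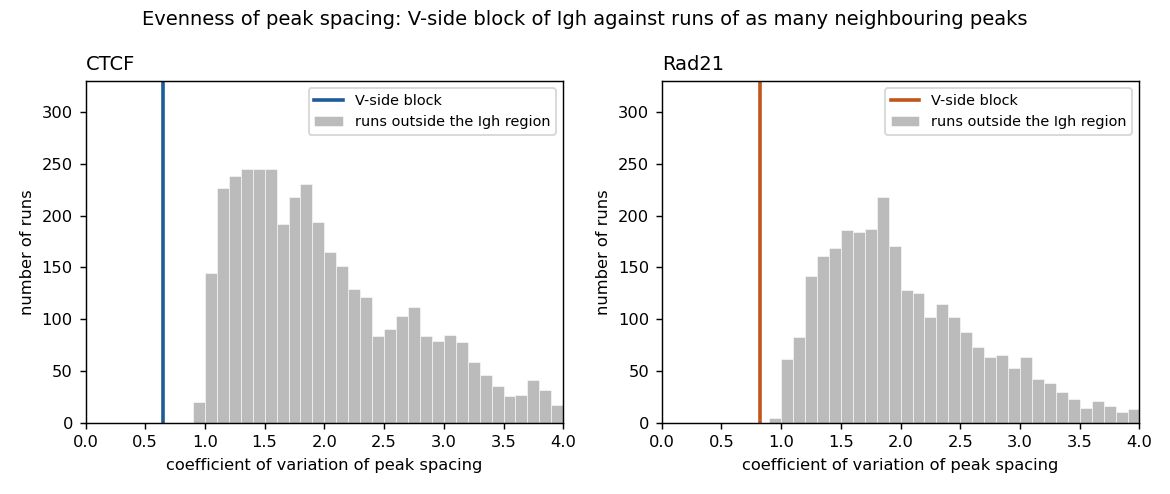
Number of runs of neighbouring peaks (vertical axis) by the coefficient of variation of their spacing (horizontal axis, no unit), for CTCF runs of 132 peaks and Rad21 runs of 131 peaks elsewhere in the genome; vertical lines mark the V-side block of Igh, at 0.647 and 0.822. The axis ends at 4, and 130 CTCF runs and 83 Rad21 runs lie between 4 and 6. Runs above 6 are not in these counts.

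The other antigen receptor loci were set beside Igh, the receptor locus that recombines in pro-B cells. The region of Tcra and Tcrd, the T cell receptor alpha and delta loci (chromosome 14, 52000001 to 55000000), was as dense in CTCF peaks as Igh, with 146 peaks (123 to 172), or 48.7 per Mb. It held 104 Rad21 peaks (85.0 to 126), or 34.7 per Mb. The Igk light chain region (chromosome 6, 67000001 to 71000000) held 53 CTCF and 45 Rad21 peaks, or 13.2 and 11.2 per Mb, close to the genome density. The Tcrb region (chromosome 6, 40000001 to 42000000) held 38 and 28 peaks. The Igl region (chromosome 16, 19000001 to 20000000) held 12 and 10, and the Tcrg region (chromosome 13, 19000001 to 20000000) 15 and 12. Of the CTCF peaks, 67.9% (53.7 to 80.1) overlapped Rad21 in Igk, 66.4% (58.2 to 74.0) in Tcra and Tcrd and 65.8% (48.6 to 80.4) in Tcrb. The shares were 83.3% (51.6 to 97.9) in Igl and 66.7% (38.4 to 88.2) in Tcrg. These 5 intervals include the share in the rest of the genome, and the Igh interval over the full CTCF list does not.

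**Figure D4:**
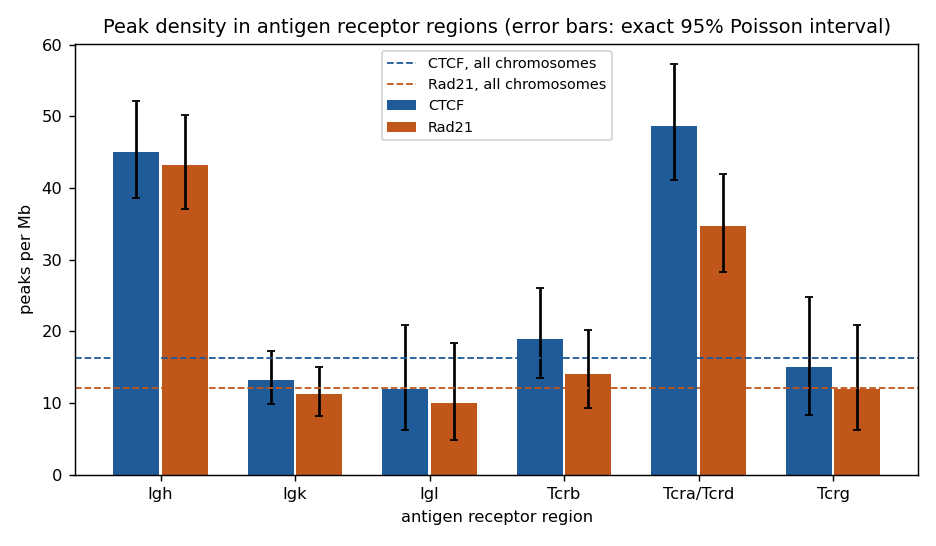
Peaks per Mb of the CTCF and Rad21 lists in each antigen receptor region; error bars are exact Poisson 95% intervals, and dashed lines the density over all chromosomes (16.3 and 12.1). Igh (45.0 CTCF and 43.2 Rad21 peaks per Mb) and Tcra/Tcrd (48.7 and 34.7) stand above the other regions.

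Along the chromosomes, peak density over the span from the first to the last peak was compared among the autosomes and X. It was highest on chromosome 11 for both proteins, with 27.7 CTCF and 20.2 Rad21 peaks per Mb, and lowest on X, with 6.31 and 4.12. The lists held 0 CTCF peaks and 1 Rad21 peak on Y. The densest 1 Mb window of both lists was chromosome 10, 80000001 to 81000000, with 101 CTCF and 74 Rad21 peaks. The next CTCF windows were chromosome 17, 35000001 to 36000000 (90 peaks), chromosome 7, 52000001 to 53000000 (89 peaks), chromosome 10, 79000001 to 80000000 (87 peaks) and chromosome 17, 34000001 to 35000000 (85 peaks). For Rad21 the next windows were chromosome 11, 98000001 to 99000000 (61 peaks), and chromosome 10, 79000001 to 80000000 (59 peaks), and the Igh window and chromosome 17, 34000001 to 35000000, each held 58. On X there were 65.2 Rad21 peaks per 100 CTCF peaks (59.1 to 72.0), against 74.5 on the autosomes. CTCF peaks on X overlapped Rad21 in 57.1% (54.0 to 60.1), against 64.8% (64.4 to 65.3) on the autosomes. Median scores on X were also lower, at 174 against 219 for CTCF and 112 against 153 for Rad21.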

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

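The restriction to the V-side block, the density, Igh share and spacing results with the top 50% of a list by score, and the spacing with merged peaks or with gap-bounded runs were chosen after the data were seen. No paired analysis was possible because each antibody has 1 library. Of 57 alternatives over 23 results, 25 stayed within the counting interval, or within 1.5 times for a count, and 32 moved further. No cause was tested beyond what each setting does by construction. Requiring 50% of both peaks to overlap lowered the shared CTCF share to 44.8%, the shared Rad21 share to 60.3% and the CTCF share in Igh to 63.9%. Centres within 200 bp gave 63.3% for CTCF and 85.2% for Rad21, and peaks set to 200 bp gave 63.3% and 85.2%. A gap of up to 1 kb gave 67.3% and 89.1%. Taking the same number of top peaks from both lists gave 73.3% and 73.9%, where equal lengths make the shares nearly equal by construction. The top 50% of both lists gave 87.2% for Rad21. Random overlap within occupied bins was 1.82% and 2.46%. The top 50% by score leaves fewer peaks by construction: 20910 CTCF and 15535 Rad21 in all, 106 and 88 in Igh, 23 and 25 in Igk, 17 and 13 in Tcrb, 5 CTCF in Igl, 44 Rad21 in Tcra and Tcrd and 9 CTCF in Tcrg. Igh then exceeded 97.2% of windows for CTCF, and 94.3% of its 106 CTCF peaks (88.1 to 97.9) overlapped the full Rad21 list, an interval that includes the 89.9% of the rest of the genome, so the excess in Igh was not resolved there. With 100 kb windows, the median Igh window exceeded 79.3% (CTCF) and 80.2% (Rad21) of windows. With the top 50% of peaks the block was less evenly spaced, with coefficients of variation of 1.14 for CTCF and 0.980 for Rad21. Runs elsewhere then went down to 0.847 and 0.815, and simulated random positions had 1.01. Of other such runs 6.89% for CTCF and 2.03% for Rad21 were as even, while merging peaks within 1 kb left none. Among stretches bounded by wide gaps in other windows, none was as even for CTCF and 1.97% for Rad21, and of runs with no longer distance than the block (32 for CTCF, 1 for Rad21) none was. Alternatives for promoters, gene lists, motifs and V gene distances were not run, since no mm9 annotation or sequence was used. The lists hold no counts, so an effect of depth could not be examined.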

Other observations

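Chosen after the results were seen were the comparisons of receptor regions and of Rad21 scores with score-matched peaks, those of the strongest CTCF peaks and of dense groups, the share in the top 50% of the CTCF list, every test of the offset in Igh, the test of reads that map to several V segments, and that of the dense group on X. The Tcra and Tcrd region and the Igh region, alike in CTCF density, differed in their Rad21 peaks. In Tcra and Tcrd the CTCF peaks were strong, with a median score of 420 and 71.2% of them in the top 50% of the list. Of these CTCF peaks 66.4% overlapped Rad21, against a mean of 76.2% for 10000 draws of CTCF peaks elsewhere with like scores, and 2 draws were as low. In Igh, 81.7% overlapped Rad21 against a mean of 69.7%, and no draw was as high (highest 80.0%). The share was 83.3% against 58.8% in Igl (12 peaks, 56 draws as high), 67.9% against 61.0% in Igk, 65.8% against 62.5% in Tcrb and 66.7% against 64.6% in Tcrg, the last 3 inside the central 95% of draws. Seen from the Rad21 list, peaks of Tcra and Tcrd overlapped CTCF more often than matched ones, in 93.3% against 86.0% (0.9% of draws as high). Where a CTCF peak had Rad21 over it, the median Rad21 score was 142 in Tcra and Tcrd, below all of 2000 draws of pairs with like CTCF scores (median 238, central 95% 188 to 294). In Igk it was 227 against 150, with 18 draws as high, and in Igl 280.5 over 10 pairs against 126, with 3 draws as high. In Igh it was 179 against 170, inside the central range of 143 to 200. In Tcrg it was 232 over 10 pairs against 152, with 119 draws as high, and in Tcrb 143 against 148, inside the central range of 106 to 214. Of the 6 regions, Tcra and Tcrd alone lay below its central range, in 1 library of each protein. The draws took single peaks from anywhere else, whereas the peaks of a region are neighbours. Variation between whole regions is therefore not in the range of the draws, which may be too narrow. These are values from several regions, looked at together, and no biological explanation was tested.

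Among the 100 CTCF peaks of highest score, 26 had no Rad21 peak over them, so 74.0% were shared (Wilson 95% interval 64.6 to 81.6), against 96.5% of those ranked 2001 to 4182. The peak ranked second, chromosome 17, 48237626 to 48238485, was one of these 26. In the highest-scoring 10% of the Rad21 list, 9 of 3107 peaks lacked CTCF. On X, 29 CTCF peaks lay between 47900001 and 48000000, and 3 of them overlapped Rad21. On chromosome 9, between 2999971 and 3038457, lay 15 Rad21 peaks with a median width of 1302 bp, scores from 50.7 to 126 and no CTCF peak. The median width of the Rad21 list was 308 bp and its lowest score 50, so these peaks were unusually wide and weak. Those at 3018285 to 3020610 (2326 bp), 3005352 to 3007545 (2194 bp) and 3011267 to 3013275 (2009 bp) were among the 5 widest Rad21 peaks. Mappability was not examined for either group, so mapping artefacts stay open.

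In the V-side block of Igh, Rad21 peaks lay on the lower-coordinate side of the CTCF peak they overlapped in 75 of 111 pairs, 67.6% (exact 95% interval 58.0 to 76.1), against 14 of 32 pairs in Igh below the block, 7 of 25 in Tcrb, 16 of 36 in Igk, 60 of 97 in Tcra and Tcrd and 7 of 10 in both Igl and Tcrg. A chance run was rare but stays open for a pattern picked after it was seen: 0.0406% of 24647 overlapping runs of as many pairs, all in 1 place, were as one-sided (most 68.5%), and with the top 50% of both lists (35 of 51 pairs) 1.01%, in 10 places (most 76.5%). A shift of a whole library was argued against by the 50.1% of pairs outside Igh with Rad21 on that side. CTCF peaks cut short where reads do not map uniquely stay open: those shared with Rad21 had a median width of 500 bp in the block, inside the central 95% of score-matched draws (470 to 537 bp), but a peak cut short also loses score, so this does not decide. Rad21 reached past the lower edge of the CTCF peak in 35.1% of block pairs (26.3 to 44.8), against 17.8% outside Igh. Past the upper edge it reached in 19.8% against 17.5%. Such a difference also follows from the offset itself, so it does not decide either. CTCF sites that face the same way are a candidate explanation and stay open too: 71.01% of 69 pairs with CTCF in the top 50% had Rad21 on the lower side, but motif strand needs the mm9 sequence, so no biological explanation was tested.

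CTCF peaks of the V-side block overlapped Rad21 in 84.1%, more often than elsewhere, but with the top 50% of the CTCF list the 94.5% of the block (86.6 to 98.5) was not resolved from 89.9% outside Igh. Their scores were argued against as the whole cause, since the highest of 10000 score-matched draws was 82.6% (mean 68.9%), and so were their widths, with a highest width-matched draw of 78.8%. These draws took single peaks and not neighbouring ones, so variation between regions is not in their range. Random placement of Rad21 inside the block gave at most 7.58% in 100 placements, so chance overlap made up little of the 84.1%. Such placement also gave a low share over the genome (1.05% for CTCF), so a high share could hardly have come out of this test. It says nothing about Rad21 peaks being more often called at CTCF sites in the block (131 Rad21 and 132 CTCF peaks, against 74.3 per 100 in the genome). Reads that map to several V segments could lower CTCF scores and so make the matched peaks too weak, and scores raised by a factor of 2 would account for the share. That cannot be told apart from a true excess without the mappability of mm9, and no biological explanation was tested.

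X had fewer Rad21 peaks per CTCF peak than the autosomes. Score-matched autosomal CTCF peaks overlapped Rad21 in a mean of 60.1%, so lower scores under a single threshold may account for part of the lower share. The draws reached down to 55.1%, below the 57.1% of X. Only 1.18% of them were as low as X, so whether scores account for the rest stays open. The number of Rad21 peaks per CTCF peak was not itself compared with these draws. The dense group on X was argued against as the whole cause, because without that 100 kb window the share was 58.4% (55.4 to 61.5), still below 64.8%. X was below every autosome both in Rad21 peaks per CTCF peak and in the share of CTCF peaks overlapping Rad21. The spread between chromosomes stays open. The lowest autosome had 69.8 Rad21 peaks per 100 CTCF peaks, inside the interval for X of 59.1 to 72.0, which may be too wide. For the share, the lowest autosome, chromosome 5, had 60.2% (58.4 to 62.0), just above the interval for X of 54.0 to 60.1. Both intervals overlap, so the share does not decide either. No biological explanation was tested.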
